A study of Homo sapiens with 10 samples.

How the data were processed

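The series profiled messenger RNA in MDA-MB-231, a triple-negative human breast cancer cell line, in 2 parts of the same cells. Per the labels' protocols, single cells were held in an array by micro-hooks on a microfluidic chip, extended protrusions during an incubation of 6 h, and were fixed on ice in 4% paraformaldehyde for 15 min. Protrusions and cell bodies were then cut out separately by laser capture microdissection, and polyadenylated RNA was amplified with a SMART-Seq v4 kit for ultra-low input before sequencing on an Illumina HiSeq instrument. There were 5 libraries of cell protrusions and 5 libraries of the corresponding cell bodies, numbered 1 to 5 in each group. The labels do not say how many cells entered a library or that the libraries came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

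The submitters' processing notes name cutadapt 1.10, FastQC 0.10.1, HISAT2 and StringTie 1.3, without their role or order. The genome build, the gene annotation and the strand setting are not given in the sources used here. The deposited table has 1 entry for each of 26134 Ensembl gene identifiers, paired with a symbol and a class of gene, and 112 symbols belong to more than 1 identifier. No source names the unit of the expression values. The unit was inferred from the values: in each library 100% of the values below 2 were whole multiples of 1 step within a tolerance of 0.00051, where an unrelated set of values would give 7.34% to 13.8%. The step matched TPM to 2 decimals multiplied by 1 factor per library, and the product of the 10 factors was 1.00. The expression values are therefore called scaled TPM here, as the deposited numbers appear to be TPM that the authors rescaled between libraries, a step that no label records. The mean factor was 0.891 ± 0.138 (SD, n = 5) in protrusions and 1.14 ± 0.177 (SD, n = 5) in cell bodies. TPM keeps no read depth, so the depth of each library is unknown, and no counting interval or detection floor is given. The same table holds the authors' log2 fold change, cell body relative to protrusion, their mean abundance on a log2 scale, and the p-value and false discovery rate of the authors' comparison, per the file headers, with the test behind them not given in the sources used here.

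The deposited values were used as given. Groups and numbers came from the labels. Genes with 1 or more in at least 5 of the 10 libraries were tested, which left 10894 genes, of which 9072 were protein-coding. Differences were fitted with limma 3.58.1 in R 4.3.3 on log2(value + 1) with a mean-variance trend, without robust fitting and without a block, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Every adjusted p of a gene in the text comes from limma unless another test is named. Fold changes are protrusion minus cell body on the log2(value + 1) scale, which understates the change of genes with low values. The number of genes at 1 or more per library was compared by an exact two-sided permutation test over all ways to divide the libraries. Because the deposited unit was not read counts, no count model was run. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the other steps.

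Before the data were examined, 22 gene lists were fixed: messages reported in protrusions of other cells, cytosolic ribosomal proteins, translation factors, transcripts of the mitochondrial genome, nuclear genes of oxidative phosphorylation, mitochondrial ribosomal proteins, the actin cytoskeleton, focal adhesions, microtubules and motors, Rab GTPases, RNAs retained in the nucleus, the translocon and chaperones of the endoplasmic reticulum, secreted and matrix proteins, glycolysis, the proteasome, mitosis, immediate early genes, heat shock proteins, and markers of luminal epithelium, keratinocytes and blood cells, with 1 further list that entered the tests but is not reported here. The 19 lists with 5 or more tested genes entered camera of limma with a preset inter-gene correlation of 0.01, adjusted over the 19 lists. Camera with an estimated correlation was the alternative, and fry was run beside it. Also fixed were the genes to be named: the 10 largest changes in each direction among genes past the threshold whose groups did not overlap, up to 4 members of each list with the smallest p, and RAB13, NET1, KIF1C, TRAK2, DYNLL2, PKP4, ACTB, MALAT1 and NEAT1 whatever their values. Identifiers with no gene symbol were left out of the naming. After the values had been seen, this was read as leaving out clone-based names and family labels shared by many loci, but keeping symbols that belong to 2 identifiers. Without a gene symbol in that sense were 31 of the genes called higher in protrusions and 718 of those called higher in cell bodies.

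The shared numbers were checked for pairing, as the series design speaks of corresponding cell bodies. After subtracting the group means, same-numbered libraries correlated across genes at 0.236, 0.577, 0.392, 0.329 and 0.264 for numbers 1 to 5, and each was highest with its own number. All 5 exceeded 0.1, the bound set beforehand, so the numbers were taken to pair the libraries. The counts of calls with the block had been seen in a first look at the data before this bound was applied, but the bound left no choice. The fit with the replicate number as a block remained the alternative, as fixed. The main fit therefore leaves the variation between replicate numbers in its error. It called 466 genes higher in protrusions against 1412 with the block, and 2340 higher in cell bodies against 2769. A gene or list said not to pass in the main fit may thus pass with the block.

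The alternatives fixed beforehand were the replicate block, pseudocounts of 0.1 and 5, no filter, a filter of a mean of 10 or more, rescaling of each library to the same sum, quantile normalization, median-of-ratios scaling, array weights, an exact Wilcoxon test per gene and leaving out each library in turn. Added after seeing the data were fits without both libraries numbered 2, with protein-coding genes alone, and with the block and an estimated correlation together. The fit was tested on simulated data for the 10894 genes: with 5 libraries per group it recovered 4.48% of 67 genes changed by 0.5 on the log2 scale, 50.7% of 67 genes changed by 1 and 97.0% of 66 genes changed by 2, and called 0.0656% of unchanged genes. The proteasome list was also shifted by 0.5. Far fewer genes were changed than the 2806 called in the data, and values were drawn independently, without pairing. Recovery under the Benjamini-Hochberg method depends on the share of changed genes, so these rates do not carry over to the data. Exon overlaps, gene lengths and positions inside other genes came from the GENCODE release 29 annotation, in which 24476 of the 26134 identifiers had an entry. Because strand use is not stated, the values of overlapping and antisense genes are uncertain.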

Results

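Gene expression was measured in 10 libraries from MDA-MB-231 cells, 5 of cell protrusions and 5 of the corresponding cell bodies, collected to find RNAs enriched in protrusions. Values are scaled TPM, given as mean ± SD over n = 5 libraries per group. The deposited values of a library summed to 891356 ± 138223 in protrusions and 1142749 ± 176592 in cell bodies, and the read depth behind them is unknown. Across genes, which are not independent replicates, the log2 values of 2 protrusion libraries correlated with a median of 0.958, those of 2 cell bodies with 0.966, and those of a protrusion and a cell body with 0.879. The first principal component held 68.2% of the variance and separated the groups, with protrusion replicate 2 the protrusion nearest to the cell bodies at 24.3, against 58.8 to 72.2 for the other protrusions.

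The number of genes detected per library was lower in protrusions than in cell bodies. At 1 or more, a protrusion library held 9516 ± 542 genes and a cell body library 11292 ± 188, with ranges of 9124 to 10471 and 11035 to 11519. The difference of -1775.6 genes was larger than the spread between libraries (exact two-sided permutation p = 0.00794, the smallest the 10 libraries can give). In the paired test on the replicate numbers as a block, every number had fewer genes in its protrusion, and the exact sign-flip p was 0.0625, the smallest that 32 sign patterns can give. The cut-off of 1 is in scaled TPM, with mean factors of 0.891 in protrusions and 1.14 in cell bodies, so it was stricter in protrusions. Above 0, where the factors play no part, a protrusion library held 17161 ± 861 genes and a cell body library 20493 ± 544. The ranges were 16236 to 18076 and 19875 to 21063. Unknown read depth may contribute to both differences.

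RAB13, a small GTPase of vesicle trafficking, was the most clearly enriched message in protrusions, at 247 ± 45.5 against 40.3 ± 8.34 in cell bodies, a log2 change of 2.59 ± 0.18 (SE, adjusted p = 3.22e-07). NET1, a guanine nucleotide exchange factor, stood at 8.33 ± 3.09 against 2.82 ± 0.457 (log2 change 1.25, adjusted p = 6.54e-04). RASSF3, a Ras-association domain protein, stood at 3.24 ± 1.07 against 0.922 ± 0.169 (1.11, adjusted p = 8.30e-04). ANP32B, an acidic nuclear phosphoprotein that binds histones, was at 64.6 ± 24.9 against 27.2 ± 5.39, a log2 change of 1.16 (adjusted p = 0.00169). Each of these 4 genes was higher in all 5 protrusion libraries than in any cell body library.

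In all, 466 genes were higher in protrusions, 430 of them protein-coding, and most changes were small: 24 exceeded 1 on the log2 scale and 3 exceeded 2. OVCA2, a serine hydrolase, had the largest change at 3.11, from 8.51 ± 7.82 in cell bodies to 52.1 ± 16.2. Its cell body values ranged from 0 in replicate 2 to 18.9 in replicate 3, so the size of this change rests partly on single libraries. All of its exons (100%) are shared with DPH1, so its reads are uncertain, and a second OVCA2 identifier had a log2 change of -0.01. GATC, a subunit of the mitochondrial glutamyl-tRNA amidotransferase, rose by 2.61 from 0.525 ± 0.415 to 8.76 ± 3.46 under 1 identifier. It shares 68.3% of its exons with a second GATC identifier at 16.1 ± 1.90 in protrusions and 19.5 ± 1.77 in cell bodies (log2 change -0.26, adjusted p = 0.266). Among genes with a symbol kept by the naming rule and groups that did not overlap, the other largest changes were in the colipase-like CLPSL2 (6.70 ± 2.17 against 2.20 ± 1.07), the plasma glycoprotein A1BG (1.08, with 40.5% of its exons shared with another gene), the mitochondrial dicarboxylate carrier SLC25A10 (1.05) and APOPT1 (1.05, with 13.1% shared), which acts in the assembly of cytochrome c oxidase. For SLC25A10 the adjusted p of 0.0206 became 0.063, 0.0694 and 0.06 without cell body replicates 1, 2 and 5. The count of genes higher in protrusions depended on the scaling and the pairing. It was 1412 with the replicate block, 1530 with each library rescaled to the same sum, 1892 after quantile normalization and 1118 with median-of-ratios scaling. With the block 2769 genes were higher in cell bodies, and 33.8% of the calls were higher in protrusions. The count higher in protrusions was 257, 263, 302 and 189 without cell body replicates 1, 2, 4 and 5. The share of calls that were higher in protrusions was 16.6% as deposited and 46.0%, 51.9% and 35.4% under the 3 scalings, which moved the median log2 change of all tested genes from -0.03 to 0.25, 0.25 and 0.09.

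In the opposite direction, MALAT1, a long RNA of nuclear speckles, fell from 85.2 ± 41.0 in cell bodies to 7.01 ± 10.3 in protrusions, a log2 change of -4.09 ± 0.61 (SE, adjusted p = 9.44e-05). Protrusion replicate 2, at 25.2, raised this protrusion mean, as the other protrusions lay between 0.288 and 5.06. NEAT1, the scaffold RNA of paraspeckles, fell by 1.74 on the log2 scale, from 4.87 ± 1.78 to 0.879 ± 1.07 (adjusted p = 4.86e-04). All 5 protrusion libraries were below all 5 cell body libraries for these 2 genes.

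In all, 2340 genes were higher in cell bodies, 1532 of them protein-coding, and many changes were large: 1837 exceeded 1 on the log2 scale and 823 exceeded 2. Among genes with a symbol kept by the naming rule and groups that did not overlap, the largest was in C14orf23, at 2.20 ± 3.55 in protrusions and 226 ± 79.5 in cell bodies (-6.65, adjusted p = 4.46e-07), a gene classed as protein-coding in the deposited table and as a long non-coding RNA in the reference annotation. Within the same limit it was followed by the zinc finger gene ZNF90 (-5.51), C10orf11 (-5.48), FRMPD1 (-5.27), the chemokine gene CCL5 (-5.19), the transporter gene ABCC10 (-4.97), the Ras exchange factor gene RASGRP3 (-4.96), the antisense gene OSBPL10-AS1 (-4.96), the cadherin gene CDH12 (-4.89) and ZNF347 (-4.84). CCL5 stood at 94.0 ± 38.9 in cell bodies and 2.13 ± 2.92 in protrusions, and CDH12 at 48.3 ± 19.4 and 0.619 ± 0.538. The count of genes higher in cell bodies was 1372, 1357, 1410, 1398 and 1314 without cell body replicates 1 to 5, where fewer genes passed the filter. Without both libraries numbered 2, an alternative chosen after seeing the data, 393 genes were higher in protrusions and 1288 in cell bodies. These fits still asked for 1 or more in at least 5 libraries. With a cell body library left out, genes at 1 or more in cell bodies alone could not pass. Only 9428 to 10000 genes were tested, against 10894, so these lower counts cannot be read as dependence on single libraries.

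The groups separated at many genes. The 5 values of one group lay wholly above those of the other in 377 genes for protrusions and 2000 for cell bodies, 21.8% of the tested genes. Chance gives 0.794% for unpaired libraries and no filter. Genes that passed the filter through the 5 libraries of 1 group alone cannot overlap, so the contrast with chance is overstated. In the authors' deposited table RAB13 had the smallest p-value, with a log2 change of -2.37 for cell body relative to protrusion and a false discovery rate of 0.0042. The authors' deposited table held 5 genes with a false discovery rate under 0.05 and 1698 genes (6.50%) with a p-value under 0.05. These values of the authors' deposited table are given as deposited, and the grouping of libraries behind them is in doubt, as described under the other observations.

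The share of genes higher in cell bodies differed between classes of gene, which were compared after the data had been seen. It was 90.0% of 20 microRNA genes, 89.9% of 109 genes of the miscellaneous RNA class, 86.5% of 37 sense-intronic genes, 51.0% of 437 long intergenic non-coding genes, 46.0% of 163 processed transcripts, 43.8% of 381 antisense genes and 29.2% of 599 pseudogenes. It was 16.9% of 9072 protein-coding genes and 3.03% of 33 small nuclear RNA genes. The median log2 change was -5.28 for the microRNA class, -3.18 for the miscellaneous class and 0.02 for protein-coding genes. In camera all classes but the small nuclear RNAs (adjusted p = 0.178) passed with the preset correlation. Protein-coding genes were placed towards protrusions and the other passing classes towards cell bodies, each relative to the other tested genes. With an estimated correlation the camera adjusted p was 0.112 or more for the non-coding classes and 0.0138 for protein-coding genes. Protein-coding genes were compared with the non-coding genes, so their result is not separate from that of the non-coding classes. Polyadenylated RNA was selected, so values of the microRNA class cannot be read as mature microRNAs, and the overlap of intronic and antisense genes with other genes leaves their values uncertain.

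**Figure D1:**
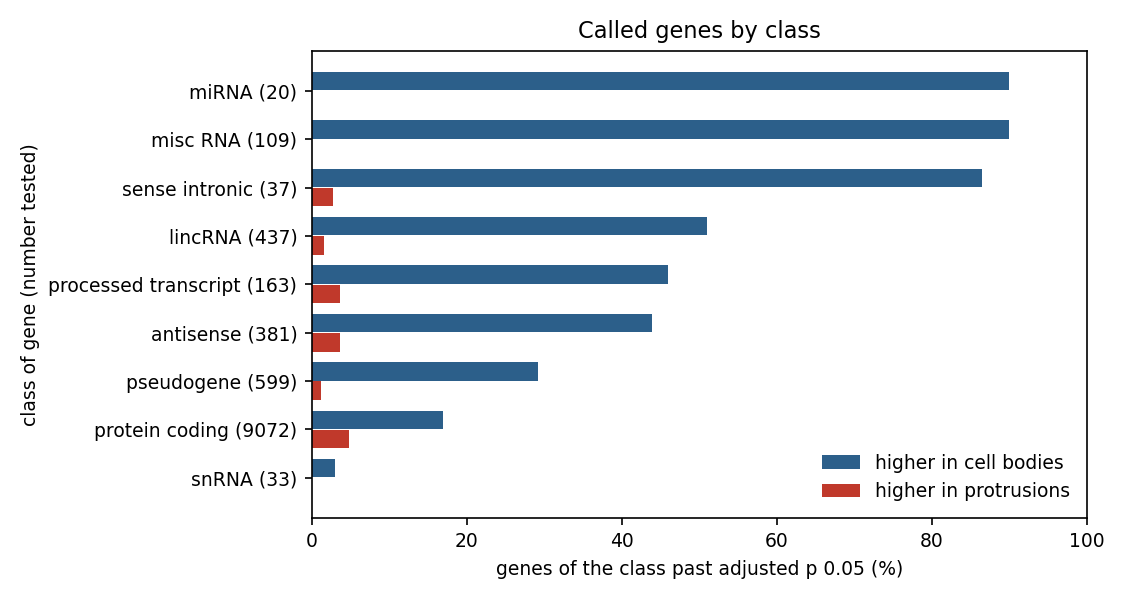
Share of tested genes past an adjusted p of 0.05, in percent, for each class of gene (number tested in parentheses), with blue bars for genes higher in cell bodies and red bars for genes higher in protrusions, 5 libraries per group. The blue bars reach 90.0% for the microRNA class and 16.9% for protein-coding genes.

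The list of messages reported in protrusions of other cells held 12 genes, of which 10 were tested, and 4 rose, 1 fell and 5 did not pass. RAB13, NET1, RASSF3 and the kinesin gene KIF1C rose, the last at 2.53 ± 0.881 against 1.05 ± 0.171 (log2 change 0.75, adjusted p = 0.0114, and 0.0506 without both libraries numbered 2). KANK2, which encodes a scaffold of adhesions and the cell cortex, was 3.44 ± 1.41 in protrusions and 35.6 ± 11.4 in cell bodies, a log2 change of -3.06 (adjusted p = 1.09e-06). DYNLL2, a dynein light chain gene, had a log2 change of 0.40 (adjusted p = 0.246, and 0.0443 with each library rescaled to the same sum and 0.00732 after quantile normalization), and the plakophilin gene PKP4 one of 0.15 (adjusted p = 0.632, and 0.0252 after quantile normalization). TRAK2, a mitochondrial transport adaptor gene, was below the filter, at 1.20 ± 0.813 in protrusions and 0.199 ± 0.0558 in cell bodies, and passed in the fit with no filter (adjusted p = 0.0319). With the replicate block 6 rose and 1 fell, and 6, 7 and 5 rose and 1 fell with each library rescaled to the same sum, after quantile normalization and with median-of-ratios scaling. Adjusted over the list alone, 5 rose and 1 fell. The median log2 change of the list was 0.51, and camera placed it higher in protrusions (adjusted p = 0.0093, and adjusted p = 0.375 with an estimated correlation).

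**Figure D2:**
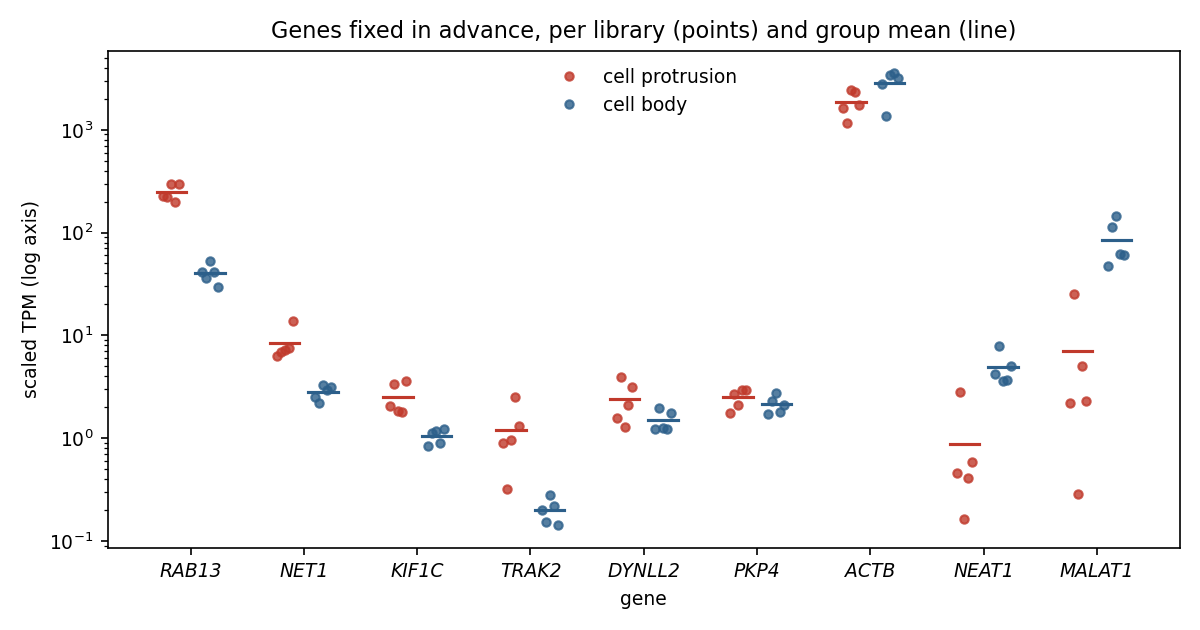
Scaled TPM on a log axis of 9 genes fixed before the data were examined, with points for the 5 protrusion libraries (red) and the 5 cell body libraries (blue) and lines for the group means. The points of RAB13 lie between 197 and 297 in protrusions and between 29.7 and 52.5 in cell bodies, and MALAT1 of protrusion replicate 2, at 25.2, lies above the other protrusions.

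Of the 8 RNAs listed as retained in the nucleus, 4 were tested, which is too few for the list test, and 3 fell in protrusions, also adjusted over the list alone. Beside MALAT1 and NEAT1, PVT1 was at 16.998 ± 5.35 against 30.1 ± 9.53 (log2 change -0.79, adjusted p = 0.0272). PVT1 missed the threshold under each of the 3 scalings (adjusted p = 0.0537 to 0.242) and without protrusion replicates 1 or 4 or cell body replicates 2 or 5 (0.0722 to 0.1), and passed with the replicate block. TUG1 was at 1.43 ± 0.439 and 1.47 ± 0.240 (-0.04, adjusted p = 0.907), with a change of opposite sign under the 3 scalings.

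Of the 7 lists that camera placed higher in protrusions relative to the other tested genes, 3 were of mitochondria or protein synthesis. The tested genes were skewed towards cell bodies, with 1837 calls beyond 1 on the log2 scale there against 24 towards protrusions. Camera can therefore place a list higher in protrusions although its genes hardly changed, so the medians and counts of each list are given beside it. Of 76 tested mitochondrial ribosomal protein genes, 7 rose, 0 fell and 69 did not pass. With the replicate block 31 rose and 2 fell, and adjusted over the list alone 0 passed. With each library rescaled to the same sum 32 rose, after quantile normalization 11, and with median-of-ratios scaling 24. A positive change was found in 66, with a median of 0.26. MRPS11 stood at 145 ± 16.5 against 97.9 ± 13.9 (0.56, adjusted p = 0.0119), while the calls of MRPL30 (0.84), MRPL11 (0.50) and MRPS16 (0.41) had adjusted p of 0.0249, 0.0264 and 0.0262. Camera placed this list higher in protrusions with an adjusted p of 2.58e-06, and with an adjusted p of 0.657 with an estimated correlation. Of 76 nuclear genes of oxidative phosphorylation, 4 rose and 1 fell (18 and 12 with the block, 1 and 0 adjusted over the list alone). Under the same 3 scalings 32, 18 and 11 rose and 0 fell. The median was 0.09 and the camera adjusted p 0.0114 (adjusted p = 0.779 with an estimated correlation). NDUFB9, a subunit gene of complex I, stood at 296 ± 45.4 against 185 ± 19.8 (0.66, adjusted p = 0.00394), and NDUFS7 at 283 ± 25.2 against 199 ± 28.3 (0.51, adjusted p = 0.0155, and 0.0591 without cell body replicate 5). Of 39 translation factor genes, 7 rose and 1 fell (11 and 5 with the block, 4 and 0 adjusted over the list alone, and 12, 9 and 9 rose and 0 fell under these scalings). The list had a median of 0.15 and camera adjusted p of 0.0154 (adjusted p = 0.657 with an estimated correlation). Those that rose included the initiation factor genes EIF3F (205 ± 15.8 against 138 ± 11.3, 0.57), EIF3L (0.68) and EIF3D (0.60). Leaving out 1 library ended several of these calls. MRPL30 was lost without protrusion replicate 3 or cell body replicates 3, 4 or 5 (adjusted p up to 0.0658). MRPL11 was lost without protrusion replicates 3 or 4 or cell body replicates 2 or 5 (adjusted p up to 0.0845). MRPS16 was lost without protrusion replicate 4 or cell body replicates 4 or 5 (adjusted p up to 0.0835). The list nuclear_oxphos was lost without cell body replicates 3 or 5 (adjusted p = 0.13 and 0.172), and the list translation_factors without cell body replicates 2 or 3 (adjusted p = 0.0778 and 0.0602).

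Of the other lists placed higher in protrusions, 3 were of the secretory pathway, Rab GTPases and the proteasome. Of 37 tested genes of the translocon and chaperones of the endoplasmic reticulum, 3 rose and 1 fell (10 and 3 with the block, 0 and 1 adjusted over the list alone). With each library rescaled to the same sum 15 rose, after quantile normalization 9, and with median-of-ratios scaling 9, and 1 fell under each. This list had a median of 0.24 and camera adjusted p of 0.0093 (adjusted p = 0.657 with an estimated correlation). SSR4, a translocon-associated subunit gene, rose by 0.56 from 280.2 ± 33.9 to 418 ± 85.7, the signal peptidase gene SPCS3 by 0.57 and the KDEL receptor gene KDELR1 by 0.60, with adjusted p of 0.019, 0.0304 and 0.0295. STT3B, a catalytic subunit gene of oligosaccharyltransferase, fell by 1.88 on the log2 scale, from 25.8 ± 5.48 to 6.49 ± 2.35 (adjusted p = 2.07e-05). Of 27 Rab GTPase genes, 2 rose and 2 fell (5 and 2 with the block, 2 and 2 adjusted over the list alone, and 5, 7 and 4 rose and 2 fell under these scalings). Together they had a median of 0.19 and camera adjusted p of 0.0309 (adjusted p = 0.657 with an estimated correlation). Beside RAB13, RAB5C rose (0.79, adjusted p = 0.0254, with 28.8% of its exons shared with another gene), while RAB5B (-2.45) and RAB21 (-1.22) were lower in protrusions, at 0.629 ± 0.186 against 8.20 ± 3.01 and 3.07 ± 1.19 against 8.33 ± 1.73. Of 31 proteasome genes, 0 rose or fell (9 rose with the block, 0 adjusted over the list alone, and 3, 0 and 2 under these scalings). The list had a median of 0.14 and camera adjusted p of 0.0287 (adjusted p = 0.866 with an estimated correlation). PSMD4 had a log2 change of 0.52 (adjusted p = 0.102, 0.00163 with the block, 0.0427 with each library rescaled to the same sum and 0.0317 with median-of-ratios scaling) and PSMB4 one of 0.35 (adjusted p = 0.0862, 0.0283 with the block, 0.00671 and 0.00761 under the same 2 scalings, and 0.0486 without protrusion replicate 3). Other calls ended when 1 library was left out. SSR4 was lost without protrusion replicate 1 or cell body replicates 3 or 5 (adjusted p up to 0.0709). SPCS3 was lost without protrusion replicates 1, 4 or 5 or cell body replicates 2 or 5 (adjusted p up to 0.106). KDELR1 was lost without protrusion replicates 3, 4 or 5 or cell body replicates 1, 2 or 5 (adjusted p up to 0.0999). RAB5C was lost without protrusion replicate 3 or cell body replicates 2, 4 or 5 (adjusted p up to 0.0681). The list rab_gtpases was lost without protrusion replicates 3 or 4 or cell body replicate 2 (adjusted p up to 0.0866), and with each library rescaled to the same sum (adjusted p = 0.0609). The list proteasome was lost without any of these libraries or cell body replicate 5 (adjusted p up to 0.569).

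Among genes of the cytosolic ribosome and the mitochondrial genome, the members that passed were lower in protrusions as deposited. Of 79 cytosolic ribosomal protein genes, 0 rose and 13 fell (3 and 59 with the block, 0 and 4 adjusted over the list alone). With each library rescaled to the same sum 11 rose and 8 fell, after quantile normalization 11 and 7, and with median-of-ratios scaling 2 and 4. This list had a median of -0.33 as deposited and -0.18 with median-of-ratios scaling, which turned to 0.02 with each library rescaled to the same sum and 0.05 after quantile normalization. Camera did not call the list (adjusted p = 0.0633) but did with the replicate block (adjusted p = 8.75e-09, and adjusted p = 0.785 with an estimated correlation), and without protrusion replicates 1 or 2 or cell body replicates 1, 3, 4 or 5 (list cytosolic_ribosomal_proteins, adjusted p = 4.26e-05 to 0.0377). RPS7 stood at 2317 ± 293 against 3532 ± 448 (-0.61, adjusted p = 0.00475) and RPL15 at 3669 ± 575 against 5651 ± 914 (-0.62, adjusted p = 0.00875, and 0.518 after quantile normalization). Of 13 transcripts of the mitochondrial genome, 0 rose and 2 fell (0 and 7 with the block, 0 and 1 adjusted over the list alone, and 1 and 1, 0 and 0, and 0 and 1 under these 3 scalings). Together they had a median of -0.28 that was positive at 0.07 with each library rescaled to the same sum and at 0.13 after quantile normalization. The camera adjusted p was 0.41, and 0.0345 with the block (adjusted p = 0.785 with an estimated correlation). MT-CO3 was at 13160.1 ± 2165 and 22898 ± 3113 (-0.81, adjusted p = 0.00128, and 0.858 after quantile normalization). MT-CO2 was at 19629.7 ± 4760 and 29568 ± 7195 (-0.60, adjusted p = 0.0485), a call that ended under each of the 3 scalings, with a sign that turned after quantile normalization, and without any 1 library but protrusion replicate 2 or cell body replicate 3 (adjusted p up to 0.141).

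Genes of the actin cytoskeleton went both ways. Of 56 tested, 4 rose and 3 fell (10 and 8 with the block, 0 and 2 adjusted over the list alone). When libraries were rescaled to the same sum 10 rose and 2 fell, after quantile normalization 11 and 2, and with median-of-ratios scaling 8 and 3. The list had a median of 0.16, a mean of 0.05 and a camera adjusted p of 0.0633 that passed with each library rescaled to the same sum and with median-of-ratios scaling (0.0256 and 0.0365 for the list actin_cytoskeleton). ARPC4, a subunit gene of the Arp2/3 complex, stood at 49.7 ± 5.39 against 33.5 ± 6.99 (0.57, adjusted p = 0.0269, but 0.0507 to 0.0776 without protrusion replicates 3, 4 or 5 or cell body replicates 1, 2 or 5). The actin-binding thymosin gene TMSB4X was at 11100.1 ± 1636 in protrusions and 22006 ± 3568 in cell bodies (-0.98, adjusted p = 1.93e-04, and 0.163 after quantile normalization). The profilin gene PFN1 was at 2562 ± 64.1 and 3934 ± 452 (-0.61, adjusted p = 0.00164, but 0.0831 with each library rescaled to the same sum and 0.31 after quantile normalization). ACTB, whose message is known to localise to the leading edge of other cells, was at 1866 ± 520 and 2859 ± 885, a log2 change of -0.59 (adjusted p = 0.133). ACTB was lower with the replicate block (adjusted p = 2.9e-04) and without cell body replicate 2 (0.0103).

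Of 24 focal adhesion genes, 2 rose and 7 fell (3 and 9 with the block, 3 and 7 adjusted over the list alone). There were 4 that rose and 4 that fell with each library rescaled to the same sum, 4 and 4 after quantile normalization, and 3 and 5 with median-of-ratios scaling. This list had a median of -0.19 that turned to 0.11 with each library rescaled to the same sum and 0.08 after quantile normalization (camera adjusted p = 0.761). The adaptor gene CRK (41.6 ± 4.28 in cell bodies, 12.6 ± 3.34 in protrusions), the integrin gene ITGA3 (28.0 ± 11.8 and 7.48 ± 2.70), PTK2, which encodes focal adhesion kinase (54.9 ± 17.3 and 17.2 ± 3.50), and LIMS1 fell, with log2 changes of -1.68, -1.74, -1.59 and -1.14. Of 28 genes of microtubules and motors, 4 rose and 2 fell (8 and 6 with the block, 4 and 2 adjusted over the list alone, and 10 and 1, 9 and 2, and 8 and 1 under these 3 scalings). Together they had a median of 0.09 (camera adjusted p = 0.0961). The plus-end binding protein gene CLIP1 fell by 2.14 on the log2 scale, and the dynactin gene DCTN1 was at 32.4 ± 11.2 against 16.99 ± 6.97 (0.91, adjusted p = 0.0258, but 0.066 to 0.0925 without protrusion replicate 5 or cell body replicates 1, 4 or 5).

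In the remaining lists 0 genes rose as deposited and none was called by camera. With each library rescaled to the same sum, after quantile normalization and with median-of-ratios scaling, the genes that fell were 3, 2 and 4 for mitosis and 1, 2 and 3 for heat shock proteins, with 0 rising. Under the same scalings 5, 3 and 4 glycolysis genes rose and 1, 2 and 2 fell, 1, 1 and 1 secreted and matrix genes rose and 1, 2 and 1 fell, and 0, 0 and 1 immediate early genes fell. For mitosis, 6 of 36 genes fell (2 rose and 9 fell with the block, 5 fell adjusted over the list alone), among them the survivin gene BIRC5 (64.4 ± 6.09 to 31.8 ± 4.93, -1.005), with a median of -0.04 where camera pointed up (adjusted p = 0.914) and a positive median under all 3 scalings. For heat shock proteins, 4 of 11 fell (5 with the block, 4 adjusted over the list alone), among them HSP90AA1 (1224 ± 193 to 674 ± 88.2, -0.86), with a median of -0.17 that turned to 0.18 with each library rescaled to the same sum (camera adjusted p = 0.495). For glycolysis, 2 of 20 fell (3 rose and 4 fell with the block, 2 fell adjusted over the list alone), and the median was 0.16, the mean -0.03 and the camera adjusted p 0.251. The 2 that fell were the phosphofructokinase gene PFKM (39.6 ± 14.7 to 5.10 ± 1.73, -2.71) and GAPDH (13889 ± 2141 to 9043 ± 903, -0.61), adjusted p = 0.00446 for the latter. The call of GAPDH ended with each library rescaled to the same sum (-0.25, adjusted p = 0.0522) and after quantile normalization, where the sign turned (0.15, adjusted p = 0.479). For secreted and matrix proteins, 3 of 24 fell (4 with the block, 1 adjusted over the list alone), among them the perlecan gene HSPG2 (6.01 ± 2.72 to 0.818 ± 1.01, -1.99), with a median of -0.10 where camera pointed up (adjusted p = 0.701) and the median was positive with each library rescaled to the same sum and after quantile normalization. For immediate early genes, 1 of 12 fell (3 with the block, 1 adjusted over the list alone). This list had a median of -0.34 (adjusted p = 0.761).

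Markers of other cell types were few. Of the luminal markers 5 were tested and 0 passed (1 rose with the block, 0 adjusted over the list alone). Together they had a median of -0.21 and a mean of -0.02 where camera pointed up (adjusted p = 0.761), and a positive median with each library rescaled to the same sum and after quantile normalization. Of the keratinocyte markers 2 were tested and 1 fell, also adjusted over the list alone, with 0, 1 and 0 falling with each library rescaled to the same sum, after quantile normalization and with median-of-ratios scaling. Of the blood markers 2 were tested and 2 fell, also adjusted over the list alone. Both lists were too small for the list test. The blood markers were the lysozyme gene LYZ, at 14.006 ± 5.59 in cell bodies and 0.520 ± 0.660 in protrusions (-3.32, adjusted p = 1.35e-06, with 33.96% of its exons overlapping an antisense gene), and CD68, at 22.6 ± 2.54 and 15.3 ± 3.61 (-0.55, adjusted p = 0.037, with 81.7% of its exons shared with another gene). The call of CD68 ended under each of the 3 scalings (adjusted p = 0.0843 to 0.521) and without any 1 library but protrusion replicates 2 or 3 (0.0534 to 0.114).

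**Figure D3:**
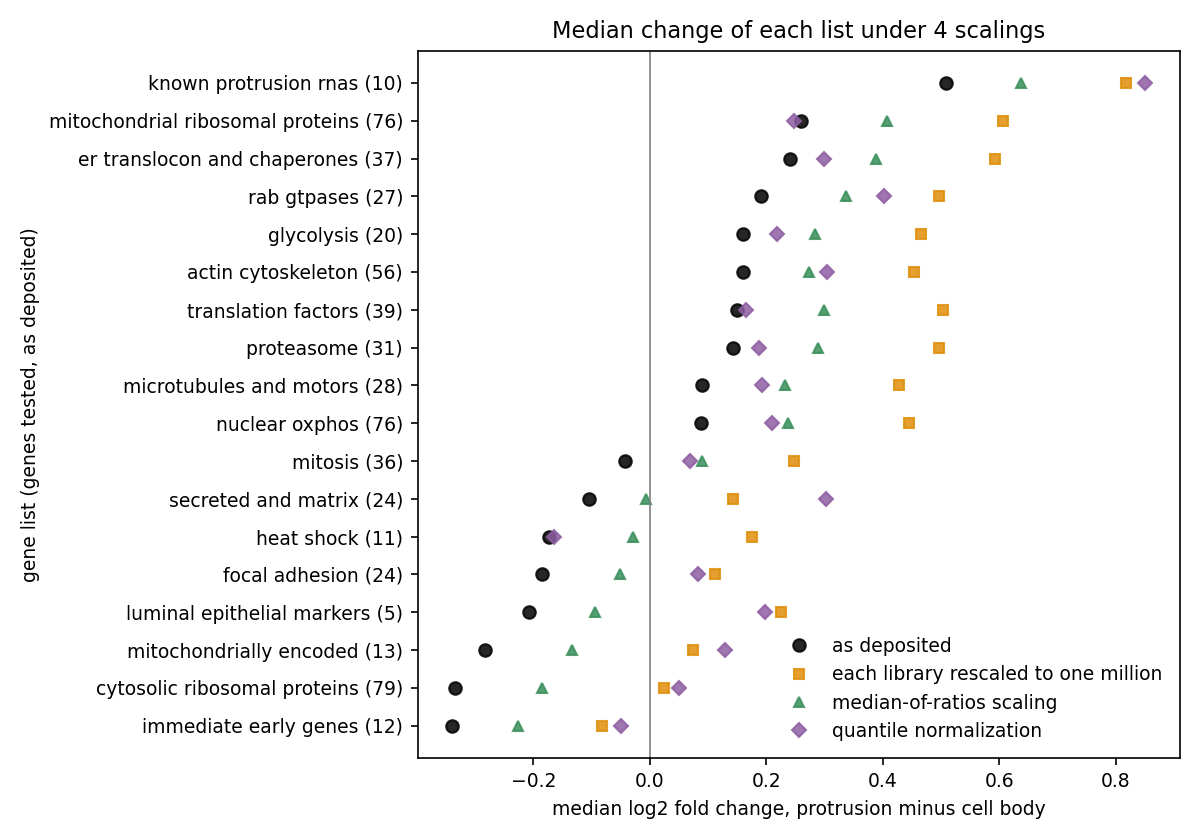
Median log2 fold change, protrusion minus cell body, of the tested genes of each reported list (number tested in parentheses), with black circles for values as deposited and coloured symbols for the 3 other scalings. The list of known protrusion messages has the highest median as deposited, 0.51, and the cytosolic ribosomal proteins (-0.33 as deposited, 0.02 with each library rescaled to the same sum) are among the lists that change side with the scaling.

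Of the 19 lists tested, of which 1 is not reported singly here, 7 were called with the preset correlation of 0.01, 9 with the replicate block, 0 with an estimated correlation and 0 after quantile normalization. Fry asks whether the genes of a list move on balance one way and compares them with no other genes. The messages known from other protrusions (adjusted p = 8.94e-04) passed it with a positive median. Heat shock proteins (adjusted p = 0.00423) and focal adhesions (0.0201) passed it with negative medians. With the replicate block these 3 lists passed, and so did the cytosolic ribosomal proteins (adjusted p = 0.00825, against 0.300 without it) and the immediate early genes (0.00859, against 0.510). The other lists that camera called with the preset correlation did not pass fry as deposited (adjusted p = 0.213 to 0.579). Fry was not run under the other scalings. With each library rescaled to the same sum the medians of heat shock proteins and focal adhesions turned to 0.18 and 0.11.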

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

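No test of this part was first thought of after its result, but 4 readings changed with the values: the coverage check of the unspliced RNA test was added, the length test was labelled by its direction, the clause on single nuclear RNAs was first left out of the label for protrusion replicate 2, and MALAT1 and NEAT1 of protrusion replicate 2 had been seen before its test was written. The counts were set beside those of 100 splits of the 10 libraries into groups of 5, the real one included. Only 1 split gave as many genes as the 466 higher in protrusions (highest other 1). Likewise 1 gave as many as the 2340 higher in cell bodies (highest other 3). The other splits put protrusions and cell bodies into both groups, which raises the spread within groups, so few calls were likely beforehand. The count of 7 lists was reached by 22 of the 100 splits (highest other 9), so chance cannot be excluded for it. Because the numbers were taken to pair the libraries, only the 13 splits that part all 5 pairs, the real one included, are comparable. Among these the highest others were 0, 0 and 6. Being the highest of 13 splits is too weak to exclude chance for the counts of genes by this test.

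Non-coding genes lay more often on the cell body side than protein-coding genes: 808 of 1822 tested, 44.3%, against 16.9%, with a median log2 change of -0.52 against 0.02. Genomic DNA spread evenly over genes in the cell body libraries is argued against as the whole cause. The 150 receptor, defensin and keratin-associated genes that should be silent gained a median of 0.0151 scaled TPM. That was 0.282% of the 5.36 gained by the called non-coding genes. The called genes were chosen for their gain, however, and 113 of the 150 had a higher mean in cell bodies. A smaller contribution of DNA, or DNA amplified unevenly, was not tested. Weaker detection of low genes in protrusions as the whole cause is argued against too, as -0.52 lay below the central 95% of 1000 sets of protein-coding genes matched on level (-0.14 to -0.08). Unspliced nuclear RNA cannot be told apart from the other causes: genes inside and outside protein-coding genes differed by -0.00197 in median log2 change (permutation p = 0.931), but only 74.6% of the called genes have a reference entry, and the 297 tested genes without one had a median of -1.92. Retention of non-coding RNA in the nucleus, which the cell bodies contain, may account for the pattern and was not tested apart from these.

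The most abundant protein-coding genes had lower log2 changes as deposited than genes of middle level, by a mean of -0.25 between 437 genes of mean log2 level 8 or more and 2242 genes between 4 and 8. Gene length is argued against, as taking it out made the difference larger, -0.30, a reduction of -20.6% (95% interval -31.2% to -12.8%). The size exceeded the 10% bound written beforehand for a length effect to be absent, but in the opposite direction from a length cause. The difference itself was not tested against no change, and a biological difference between protrusions and cell bodies remains open and untested.

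Protrusion replicate 2 lay closer to the cell bodies than the other protrusions, and 16 of the 24 results flagged below, out of 140 groups of 5 values of which chance flags about 1 in 20, come from that library. Cell body RNA in this library may contribute, but cannot be told apart from another state of its cells: over 832 genes, the median share of cell body RNA that its values would need was 0.0859 (quartiles 0.0399 and 0.172, with 706 genes above 0), against -0.0374 to -0.0149 in the other protrusions. Apart from the fixed nuclear RNAs, these genes were chosen as higher in cell bodies without this library. Each other protrusion was also compared with a mean that included this library. The signs of the shares were therefore largely built in, and the other protrusions are no control. The test also needed 1 common share in every nuclear RNA, and this was not met, with 0.275 for MALAT1, 0.532 for NEAT1, -0.0474 for PVT1 and 3.83 for TUG1, whose group means hardly differ. This keeps the explanation open, and another biological state of the cells was not tested.

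The groups searched were enlarged to all genes named in the text after first values had been seen. Each result that follows was flagged because 1 library lay far from the other 4 of its group, by a gap divided by the range of the group above 0.71, with the value of that library and of the nearest other in parentheses. Protrusion replicate 2 was highest for MALAT1 (0.808, 25.2 and 5.06), NEAT1 (0.84, 2.78 and 0.581), C14orf23 (0.761, 8.39 and 2.00), ZNF90 (0.807, 22.95 and 5.94), C10orf11 (0.956, 5.94 and 0.585), FRMPD1 (0.723, 17.2 and 5.90), CCL5 (0.851, 7.29 and 1.43), ABCC10 (0.952, 22.1 and 3.53) and RASGRP3 (0.858, 13.0 and 2.57). It was also highest for OSBPL10-AS1 (0.88, 1.87 and 0.223), ZNF347 (0.739, 15.7 and 6.32), EIF3L (0.75, 144 and 101), CLIP1 (0.819, 5.63 and 1.99), HSPG2 (0.846, 2.60 and 0.553), LYZ (0.722, 1.66 and 0.503) and the number of genes at 1 or more (0.811, 10471 and 9378). Cell body replicate 2 was highest for EIF3L (0.786, 86.2 and 60.7) and lowest for NDUFB9 (0.765, 151 and 187) and RAB5C (0.734, 7.42 and 13.4). Protrusion replicate 3 was highest for SLC25A10 (0.82, 27.6 and 11.7), RAB5C (0.788, 37.2 and 22.1) and CD68 (0.792, 21.7 and 14.5), protrusion replicate 5 for NET1 (0.839, 13.8 and 7.49), and protrusion replicate 4 was lowest for GATC (0.735, 2.77 and 8.93).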

How the results depend on the processing

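The fits without both libraries numbered 2, with protein-coding genes alone, and with the block and an estimated correlation together were chosen after the data had been seen. Where a result moved, the cause was not tested, except that the strict filter, the protein-coding fit and the fits without a cell body library tested fewer genes, and the fit with no filter more. A model of counts was not run, as the values are not counts.

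The genes higher in protrusions numbered 1412 with the replicate block, 1530 with each library rescaled to the same sum, 1892 after quantile normalization, 1118 with median-of-ratios scaling, and 189 to 652 with 1 library left out. The genes higher in cell bodies numbered 3975 with no filter, 601 with a mean of 10 or more, 1288 without both libraries numbered 2, 1521 with protein-coding genes alone, and 1314 to 2545 with 1 library left out. The gene lists past the threshold numbered 2 with a mean of 10 or more, 0 after quantile normalization, 0 with an estimated inter-gene correlation, 3 without both libraries numbered 2, 0 with the replicate block and an estimated correlation, and 4 to 8 with 1 library left out. The genes detected per library differed by -1775.6 with the replicate block (exact sign-flip p = 0.0625).

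Some results changed direction, which for a list means the direction in camera, with the median of its genes given here. After quantile normalization GAPDH was at 0.15, MT-CO2 at 0.0289, TUG1 at 0.38, the list cytosolic_ribosomal_proteins at 0.0494, the list mitochondrially_encoded at 0.13, the list mitosis at 0.0683 and the list luminal_epithelial_markers at 0.20. With each library rescaled to the same sum TUG1 was at 0.16 and cytosolic_ribosomal_proteins at 0.0243, and with median-of-ratios scaling TUG1 at 0.0488. With no filter focal_adhesion was at -0.10 and luminal_epithelial_markers at -0.11. With a mean of 10 or more the list secreted_and_matrix was at -0.21, glycolysis at 0.11 and mitosis at -0.0163. Without both libraries numbered 2 secreted_and_matrix was at -0.14 and mitosis at -0.0442. The list mitosis was at -0.0430 with the replicate block, alone or with an estimated correlation, and with protein-coding genes alone, and at -0.13 with array weights. With 1 library left out the ranges were -0.11 to 0.0462 for TUG1, -0.16 to 0.0145 for secreted_and_matrix, -0.12 to 0.0137 for mitosis, -0.64 to -0.0756 for the list immediate_early_genes and -0.28 to 0.0178 for luminal_epithelial_markers.

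With pseudocounts of 0.1 and 5, 66 and 67 of the 67 tested named genes kept their direction and their side of the threshold. Calls of named genes ended with array weights for SPCS3, KDELR1 and ARPC4 (adjusted p = 0.0641, 0.0581 and 0.0503). Without both libraries numbered 2 they ended for KIF1C, MRPL30, MRPS16, SPCS3, KDELR1, RAB5C, ARPC4, MT-CO2, CD68 and PVT1 (adjusted p = 0.0506 to 0.0832). With no filter they ended for DCTN1, MT-CO2 and PVT1, and MT-CO2 also ended with a pseudocount of 0.1, a mean of 10 or more and protein-coding genes alone. The exact Wilcoxon test gave 377 genes higher in protrusions and 2000 in cell bodies, and ended the calls of DCTN1, MT-CO2, CD68 and PVT1. Only genes at its smallest p, 0.00794, passed after adjustment. These are the genes whose groups did not overlap, so the test restates that criterion. Of the lists, those of translation factors, nuclear oxidative phosphorylation, Rab GTPases, the endoplasmic reticulum and the proteasome ended with a mean of 10 or more and without both libraries numbered 2. The Rab GTPases and the proteasome ended with protein-coding genes alone, and the proteasome with array weights. The replicate block brought ACTB, PSMD4, PSMB4 and the lists of cytosolic ribosomal proteins and mitochondrial transcripts past the threshold in limma and camera, and changed no other such call among the genes and lists named in the text. It also changed calls of fry, of genes detected per library and of genes not named, as given beside those results. Read depth is unknown, so what depth limits could not be measured.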

Other observations

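The test in this part was written down after a search on more abundant genes had raised its explanation, and was then run on genes that the search had not used, in the same libraries. The search used the 2623 genes with a mean value above 20, and the next 2 comparisons are limited to these. The log2 fold changes of the authors' deposited table were small for genes higher in cell bodies. Of the genes searched, 125 with a log2 ratio of group means above 4 had a median ratio of 5.05, and in the authors' deposited table their median was 1.67. For 437 genes on the protrusion side, chosen by another bound, a log2 ratio of cell body to protrusion means below -0.5, the medians were -0.62 for the ratio of means and -0.50 in the authors' deposited table. The hypothesis is that cell body replicate 2 may have stood on the protrusion side of the authors' comparison. Over 3049 genes of mean 5 to 20, the root mean square difference between the authors' deposited table and the log2 ratio of means was 0.349 with that library moved, the smallest of 1002 groupings of the 10 libraries (next 0.378), against 1.101 for the grouping in the labels (place 736). Over the 2623 genes of the search it was 0.188 against 0.889. The expression values of cell body replicate 2 lay with the other cell bodies, at a first component of -77.8, so the labels were kept.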
